A study of Mus musculus with 4 samples.

How the data were processed

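Tumour-infiltrating cells of 129S6 mice were measured in 4 libraries, 1 for each of control IgG2a, anti-PD-1, anti-CTLA-4 and the combination. Per the labels' protocols, mice received 200 µg of antibody by intraperitoneal injection on days 3, 6 and 9, tumours were digested with collagenase, and live CD45+ cells were sorted and loaded on a 10x Genomics Chromium instrument with the version 1 kit for 3′ ends. How many mice went into a library is not given in the sources used here. The digestion and the sort come before any count, so genes induced by digestion and losses of fragile cells such as neutrophils enter every library.

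The authors deposited raw UMI counts per gene and cell barcode for each library, unnormalized, as the file headers and the whole-number values show. Per the submitters' processing notes, Cell Ranger and Seurat were used with the mm10 genome; their versions, the gene annotation and the filters are not given in the sources used here. The 4 matrices held 27998 genes each and 3840, 3440, 3372 and 3966 barcodes (control, anti-PD-1, anti-CTLA-4, combination; 14618 in all). The authors also deposited a table that lists the cells passing their quality filter with 1 of 19 cluster numbers per cell, and a second table of the lymphoid cells with 12 cluster numbers. Both give numbers and no cell type. In the first table, 2 listed cells had no matrix column and 14491 were used. Of the 127 barcodes not listed, 124 had over 3000 genes, as did 5 listed cells, so the list mostly leaves out barcodes with many genes. The lowest UMI count of a listed cell was 792. Listed cells held 47589092 UMIs, with 11176246 to 13374294 per library.

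The authors' clusters were named by marker lists fixed before the data were examined, as were the groups, comparisons, gene lists, named-gene rule and alternatives in the original plan. For each cluster, genes seen in at least 25% of its cells were ranked by fold over all other cells (CPM with 1 added), and a cluster was called X-like only if at least 3 markers of that type were detected and its 10 leading genes did not hold more markers of another type. Clusters 1, 2, 4, 7 and 15 were called macrophage/monocyte-like and clusters 3, 6, 8, 9 and 10 T cell-like. Cluster 5 was NK cell-like, 11 conventional dendritic cell-like, 12 neutrophil-like, 16 plasmacytoid and 17 migratory dendritic cell-like, and 18 tumour or fibroblast-like. Clusters 0, 13 and 14 kept their numbers: cluster 0 was led by a neutrophil marker beside monocyte genes outside the lists, cluster 13 carried markers of T cells and macrophages together, and cluster 14 was led by Gzmg, Ctsg, Gzmd and Mcpt8. The names are rebuilt from markers and may differ from the authors' own.

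Shares of cells were given with exact Clopper-Pearson 95% intervals. UMI counts were summed over the cells of a class in each library and divided by the class total (CPM). Log2 ratios between libraries carry the exact conditional binomial 95% interval of a ratio of 2 Poisson counts. Macrophage/monocyte-like totals were 6835977, 4895041, 4995210 and 6395781 UMIs and T cell-like totals 2741630, 1783024, 2497062 and 3000830. A gene at 10 CPM is therefore seen as fewer than 100 counts in a class, which limits what can be told apart for low genes. With 1 library per group no test was run, no p-value is given, and a count of changed genes is not given either.

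For each of 20 gene lists and 19 cell type marker lists, the median log2 ratio was taken over members with at least 20 counts in the 2 libraries compared, with 0.5 added to each count. It was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, and its percentile is the share of random medians below it. Lists share members (Cxcl9, Ifng and Tnfrsf9 among them), so they are not independent. Shares of cells with a UMI of a gene were computed after thinning each cell to 1000 UMIs, leaving out shallower cells. Beside them are the unthinned share and the share in a class that was assumed to lack the gene.

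Genes were named by a rule. The text names every gene of a fixed key list of myeloid and T cell genes, and per comparison the 5 highest and 5 lowest log2 ratios among genes with at least 50 counts in 1 of the 2 libraries and at least 50 CPM in the higher one. It also names up to 4 members per list with the largest absolute ratio in the combination against control, and for the closing part the 5 genes that depart most from the sum of the single-antibody ratios. Of the genes this rule names, 1 key gene and 1 list member are not reported here. Genes given for free RNA, cluster identity or few-cell concentration (Lyz2, Cd3d and the leading genes of clusters) fall outside it.

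Scrublet, run per library in scanpy, marked 1 of 14491 cells as a doublet, so its own threshold did not work on these cells. In its place, an alternative chosen after seeing the data left out the 3% of cells with the highest scores in each library, 435 cells. Other alternatives were clusters made here (Leiden, resolution 1.0, on 2000 variable genes, 30 principal components and 15 neighbours, seed 1) on the listed cells or on 14602 barcodes with at least 200 genes and at most 10% mitochondrial counts, gene gates, median-of-ratios scaling, equal weight per cell, thinning to 1000 or 2000 UMIs, a minimum of 100 counts or none, and leaving out the cycling clusters. Added after seeing the data were also the removal of macrophage/monocyte-like cells with any UMI of 17 T or NK cell markers, clusters made without 470 leading genes, cluster 0 joined to the macrophage/monocyte-like class, the removal of cycling clusters for gene lists, and leaving out the 1 cell with the most UMIs of a key gene in either library. Each cluster made here took the authors' number that was most frequent among its listed cells. Of the listed cells, 73.7% kept their own number in clusters made on those cells, and 58.1% in clusters made without leading genes. Values from clusters made here partly reflect this assignment.

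The share of a ratio that the mix of clusters gives was bounded by 10000 draws of the counts, which covers counting error only. The ratio and list steps were tested on simulated data. The counts were drawn as Poisson counts from the class sums, which is the model that the interval assumes. The coverage therefore checks the calculation and does not show how the interval fares with the spread between cells. For anti-PD-1 against control in macrophage/monocyte-like cells (10125 genes, 200 of them changed), the interval covered the true ratio of 185 changed genes (92.5%) and a list made with a log2 ratio of 1 came back at 1.02. In T cell-like cells (8819 genes), 190 (95%) were covered and the list came back at 0.97. Coordinates are those of GENCODE M21 on GRCm38. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.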

Results

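Immune cells were collected from transplanted tumours of wild-type 129S6 mice, an inbred laboratory strain, and their transcripts were counted cell by cell. The mice had received 200 µg of antibody on days 3, 6 and 9 after transplant. The antibody was a control IgG2a, anti-PD-1 (clone RMP1-14), anti-CTLA-4 (clone 9D9) or both checkpoint antibodies together. PD-1 and CTLA-4 are inhibitory receptors of T cells, and the antibodies are given to relieve that inhibition. The comparisons asked how the myeloid and lymphoid cells of the tumour differed between checkpoint antibody and control, and between the combination and each antibody alone. The data held 1 library per group and 14491 cells that the authors listed as passing their quality filter. These were 3793 cells with 13374294 unique molecular identifiers (UMIs, each standing for 1 captured transcript) in the control library and 3417 cells with 11176246 UMIs in the anti-PD-1 library. The anti-CTLA-4 library had 3336 cells with 11211310 UMIs and the combination library 3945 cells with 11827242 UMIs. The median cell held 2923, 2824, 2991 and 2549 UMIs in the same order.

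With 1 library per group there was no replicate check and no test of any difference. Library, group and any batch cannot be told apart, so every comparison describes these libraries. All intervals are 95% intervals. They cover counting error only, except those of list medians, which come from the spread of the list's members.

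Macrophage/monocyte-like and T cell-like cells made up most of every library. T cell-like cells were 29.2% of listed cells in the control library (interval 27.7 to 30.7, 1107 cells). Their share was lower with anti-PD-1 (20.3%, 19.001 to 21.7, 695 cells) and with anti-CTLA-4 (23.1%, 21.7 to 24.6, 771 cells), and slightly higher with the combination (31.8%, 30.4 to 33.3, 1256 cells). NK cell-like cells, innate cytotoxic lymphocytes, were 8.17% (7.32 to 9.09) of the control library, 8.81% with anti-PD-1, 6.56% with anti-CTLA-4 and 4.13% (3.53 to 4.80) with the combination. Cluster 14 was kept apart from them but carried the NK cell markers Ncr1 and Gzma. With it the shares were 8.86%, 9.83%, 8.66% and 4.99%, and the ratio of anti-CTLA-4 to control went from 0.803 (0.673 to 0.958) to 0.978 (0.833 to 1.15). Neutrophil-like cells were 1.40% (1.05 to 1.82) of the control library and 2.94% (2.44 to 3.52) of the combination library, with 1.11% and 1.23% in the anti-PD-1 and anti-CTLA-4 libraries. Conventional dendritic cell-like cells held 2.16%, 2.43%, 2.43% and 2.61% in control, anti-PD-1, anti-CTLA-4 and combination. Plasmacytoid dendritic cell-like cells held 1.50%, 1.05%, 0.869% and 0.887%. The ratio of their share to control was 0.578 with anti-CTLA-4 (0.357 to 0.920) and 0.590 with the combination (0.376 to 0.915), and the interval for anti-PD-1 (0.701, 0.449 to 1.08) included 1. Migratory dendritic cell-like cells held 0.817%, 0.761%, 1.11% and 0.963%, with ratio intervals that included 1 in each treated library. The sort took live CD45+ cells, and a tumour or fibroblast-like cluster was 0.791% of the control library and 3 cells of the combination library.

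Macrophage/monocyte-like cells were 40.1% of the control library (38.5 to 41.7, 1521 cells), 36.8% with anti-PD-1 (1256 cells), 42.3% with anti-CTLA-4 (1411 cells) and 47.4% with the combination (45.8 to 48.9, 1868 cells). The direction of this difference depended on which cells were counted. The log2 ratio of the share to control was -0.13 for anti-PD-1 and 0.24 for the combination, and became 0.24 and -0.06 when cells were classed by single marker genes. These gates counted any cell without a Cd3 UMI that held a UMI of a C1q gene, Csf1r or Lyz2. They took in most of cluster 0, where 98.2% of cells held Lyz2, and part of other classes. The class bordered on cluster 0, which was kept apart by the naming rule because its leading genes held a neutrophil marker (Il1r2) and no macrophage marker. Its cells nonetheless carried macrophage and monocyte markers, with Ly6c2 in 65.9%, C1qb in 58.5%, Csf1r in 58.3% and Ccr2 in 56.5%. Il1r2 was in 32.0% and the neutrophil marker S100a9 in 2.33% of them, against 69.0% and 95.2% of neutrophil-like cluster 12. Cluster 0 held 13.5%, 26.2%, 19.3% and 6.79% of listed cells in control, anti-PD-1, anti-CTLA-4 and combination. Its log2 ratio in the combination was -0.99 with the deposited clusters and -0.09 with clusters made here, so no order of its shares is given. Together, macrophage/monocyte-like cells and cluster 0 made up 53.6%, 63.0%, 61.6% and 54.1% of the 4 libraries. The ratio of this joined share to control was 1.18 with anti-PD-1, 1.15 with anti-CTLA-4 and 1.01 with the combination.

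**Figure D1:**
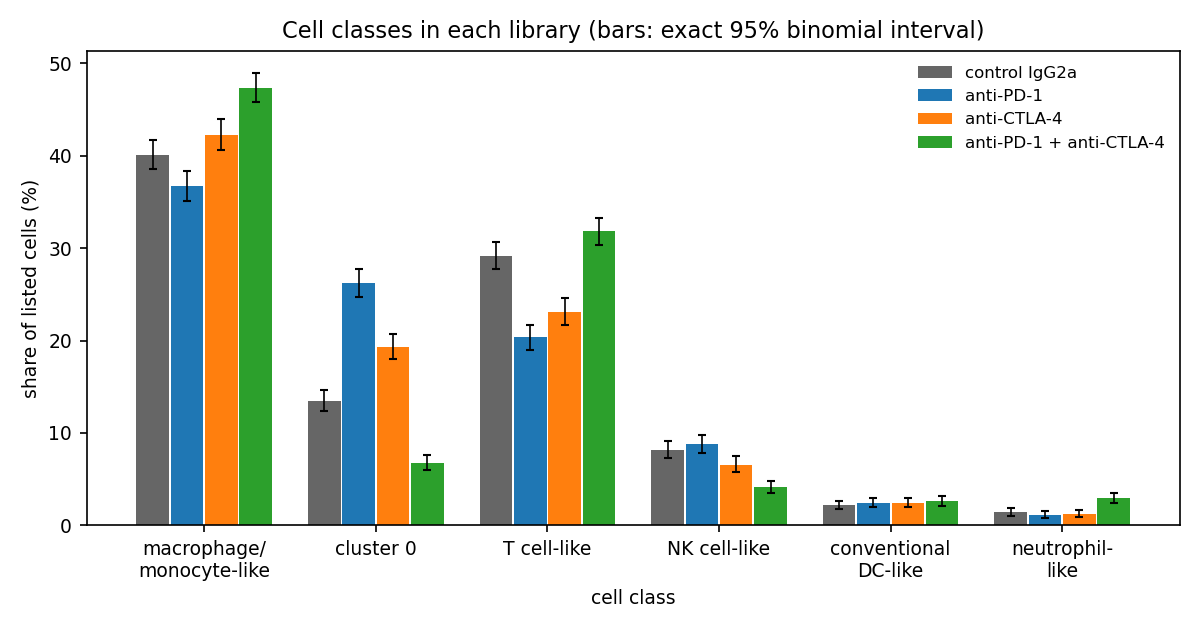
Share of listed cells (vertical axis, percent) in the larger cell classes (horizontal axis), 1 bar per library, with error bars for the 95% exact binomial interval of counting error. T cell-like cells were 29.2% of the control library and 20.3% of the anti-PD-1 library, and NK cell-like cells 8.17% of the control and 4.13% of the combination library.

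The makeup of macrophage/monocyte-like cells differed between libraries. Cluster 1, led by Cd72, Vcam1 and Cd81, held 1075 of the 1521 control cells. Cluster 2 (led by Nov, Pf4 and Ccl8) was the largest with anti-PD-1 (549 of 1256), with anti-CTLA-4 (435 of 1411, beside 417 in cluster 1) and with the combination (688 of 1868). Cluster 4 (led by Chil3 and Hp) held 589 of the combination cells and cluster 7 (led by Rsad2, Inhba and Ifit2) held 323. The cycling cluster 15 held 126 control cells and 9, 14 and 14 cells with anti-PD-1, anti-CTLA-4 and the combination. Values within the class are therefore differences of the whole class. Of the genes with ratios given here, Apoe and Arg1 are also among the 10 leading genes of cluster 2, Hp and Sgk1 of cluster 4, Rsad2 and Nos2 of cluster 7, and Ccnb1, Ube2c and Birc5 of cluster 15. Scaling by median-of-ratios size factors instead of the class total moved all genes of the class together. Relative to that scaling, the log2 ratios given here are shifted by -0.13 for anti-PD-1, -0.16 for anti-CTLA-4 and -0.21 for the combination. In T cell-like cells the shift was between -0.01 and -0.03.

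Macrophage/monocyte-like cells of the anti-PD-1 library had more transcripts of Nos2, the inducible nitric oxide synthase of inflammatory macrophages, than control cells, and fewer of Cx3cr1, the fractalkine receptor of resident and patrolling cells. Nos2 was at 52.9 CPM (the gene's UMIs scaled to the UMI total of the class; 259 UMIs) against 10.4 CPM (71 UMIs) in control, a log2 ratio of 2.35 (1.96 to 2.75). Cx3cr1 was at 23.5 CPM (115 UMIs) against 139 CPM (951 UMIs), a log2 ratio of -2.57 (-2.86 to -2.29). Arg1, an arginine-degrading enzyme of macrophages, was 2.23 higher (2.17 to 2.29), Cd274, which encodes the PD-1 ligand PD-L1, was 1.49 higher (1.35 to 1.64), and the mannose receptor gene Mrc1 was 0.65 higher (0.55 to 0.76). The ratio of Nos2 was 1.51 when cells were thinned to 1000 UMIs and 1.69 when cluster 0 joined the class.

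Interferon-induced genes were higher together in the anti-PD-1 library: all 32 measured members were above control, with a median log2 ratio of 0.59, above all 10000 random lists matched on expression (percentile 100). They included Cxcl9 (0.41) and Cxcl10 (0.57), chemokines that draw T cells. Inflammatory macrophage genes were higher in 16 of 17 members (median 0.98, percentile 100), with Il1a at 2.54 and the arginine transporter gene Slc7a2 at 1.92. Il1b was 0.40 higher, Cd40 was 0.69 higher (0.47 to 0.90) and the interval of Tnf (0.29, -0.11 to 0.69) included 0. MHC class I presentation genes were higher in 14 of 14 members (median 0.35, percentile 99.97), whereas MHC class II presentation genes had a median of -0.07 that became 0.05 under median-of-ratios scaling. Resident and alternatively activated macrophage genes were higher in 13 of 20 members (median 0.38, percentile 100), with Apoe at 0.73 and C1qa at -0.36. Monocyte genes were higher in 11 of 14 (median 0.20, percentile 98.6), with Ly6c2 at 1.24 and Hp, which leads cluster 4, at 2.24. The chemokine receptor gene Ccr2 was an exception at -0.86, and at -0.23 with cluster 0 in the class. Glycolysis and hypoxia genes were higher in 23 of 24 (median 0.68, percentile 100), including Hilpda (1.49) and Ero1l (1.42). Chemokine genes were higher in 16 of 20 (median 0.53, percentile 100), with Ccl17 at 3.53 (33 UMIs against 4), and lysosome and lipid handling genes in 16 of 20 (median 0.27, percentile 99.97), with Plin2 at 0.91. Ccl17 is also a marker of migratory dendritic cells, whose marker list had medians of 1.65, 1.36 and 1.09 in this class with anti-PD-1, anti-CTLA-4 and the combination. Type 2 conventional dendritic cell markers were at 1.59, 0.93 and 0.07 in the same order. Oxidative phosphorylation genes moved little in any treated library, with medians of 0.10, 0.13 and 0.12 for anti-PD-1, anti-CTLA-4 and the combination.

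Proliferation genes were lower in all 20 members (median -2.33, percentile 0), with Ccnb1 at -3.85 and Mcm6 at -2.56. Without the cycling cluster 15, which held 9 of these cells against 126 in control, the median was -1.10. Cytosolic ribosomal protein genes were lower in all 22 members (median -0.44) and mitochondrially encoded genes in all 10 (median -0.29). Highest and lowest ratios are given here and below among genes with at least 50 counts in 1 of the 2 libraries and at least 50 CPM in the higher one. The highest belonged to Ccl24 (7.82, 7.29 to 8.42), an eosinophil-attracting chemokine, Retnla (5.21), Nov (5.02), Chil3 (4.10) and the scavenger receptor gene Cd163 (3.79). Nov and Chil3 lead clusters 2 and 4. The lowest belonged to the B cell chemokine gene Cxcl13 (-7.41, -8.54 to -6.48), to the cell cycle genes Ube2c (-3.76), Birc5 (-2.96) and Stmn1 (-2.86), and to Slamf9 (-2.82). Cxcl13 had 9 UMIs, against 2132 in control, where 88 cells held it and the highest 10 of them held 68.0%. Retnla came from 51 cells with anti-PD-1 and 4 cells in control.

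Macrophage/monocyte-like cells of the anti-CTLA-4 library had the same directions for Nos2, Cx3cr1, Arg1 and Cd274, and the opposite one for Mrc1 and Apoe. Nos2 was 3.00 above control on the log2 scale (2.64 to 3.39; 416 UMIs, 83.3 CPM) and Cx3cr1 was at -2.39 (-2.66 to -2.12; 133 UMIs, 26.6 CPM). Arg1 was 1.84 higher (1.77 to 1.90) and Cd274 1.78 higher (1.64 to 1.93). Mrc1 was at -0.84 (-0.98 to -0.70) and Apoe, which encodes a lipid carrier, at -0.41 (-0.46 to -0.35). For Nos2 the ratio was 2.33 in thinned cells and 2.38 with cluster 0 in the class.

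Interferon-induced genes were higher in 30 of 32 members (median 0.47, percentile 100), with the antiviral gene Rsad2, which leads cluster 7, at 1.84. Cxcl9 (-0.08) and Cxcl10 (-0.15) were the 2 below control, and both turned positive (0.08 and 0.01) under median-of-ratios scaling. Inflammatory macrophage genes were higher in 14 of 17 (median 0.84, percentile 100), with Il1a at 2.83, Slc7a2 at 2.84, Il1b at 0.59, Tnf at 0.65 (0.28 to 1.02) and Cd40 at 0.63. MHC class I genes were higher in 14 of 14 (median 0.40, percentile 99.98) and MHC class II genes in 8 of 10 (median 0.02, percentile 81.0). Resident and alternatively activated macrophage genes were lower in 14 of 20 (median -0.38, percentile 0.08), with C1qa at -0.44. Monocyte genes had a median of 0.04, with Ly6c2 at 1.73 and Ccr2 at -0.73. Glycolysis and hypoxia genes were higher in 24 of 25 (median 0.77, percentile 100), with Egln3 at 1.87 and Hilpda at 2.07. Lysosome and lipid handling genes were higher in 16 of 20 (median 0.45, percentile 100), with Gpnmb at 2.23. The chemokine list was higher in 12 of 20 (median 0.58, percentile 100), with Ccl17, a ligand of CCR4, at 5.73 and Ccl3 at 1.55.

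Proliferation genes were again lower in all 20 members (median -2.01, percentile 0; -1.26 without cluster 15), and ribosomal protein genes in all 22 (median -0.33, percentile 0.08). Mitochondrially encoded genes were lower in 9 of 10 (median -0.34, percentile 2.60). Ccl24 (6.15), Retnla (5.43, from 37 cells), Nov (4.21), Apol7c (3.59) and Chil3 (3.56) had the highest ratios among genes that reached 50 CPM, which Ccl17 did not. The lowest were those of the cyclin gene Ccnd1 (-3.28), Pmepa1 (-3.25), Ube2c (-3.09), 2810417H13Rik (-2.73) and Stmn1 (-2.62).

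In the combination library, macrophage/monocyte-like cells had Nos2 at 79.6 CPM (509 UMIs), 2.94 above control (2.58 to 3.32), and Cx3cr1 at 30.3 CPM (194 UMIs), a log2 ratio of -2.20 (-2.43 to -1.97). Arg1 was 3.27 higher (3.22 to 3.33) and reached 4048 CPM against 419 CPM in control. Cd274 was 1.72 higher (1.58 to 1.86) and Mrc1 was at -1.15 (-1.29 to -1.01). The chemokine genes Cxcl9 (-2.31, -2.43 to -2.19) and Cxcl10 (-1.42, -1.59 to -1.25) were lower than in control. Thinning to 1000 UMIs brought the ratio of Nos2 to 2.07.

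The interferon-induced list was split in the combination library, with 16 of 32 members above control and a median of -0.04 (percentile 89.2) that became 0.17 under median-of-ratios scaling. Rsad2, which leads cluster 7, was at 1.05. MHC class I genes were still higher in 12 of 14 (median 0.29, percentile 99.6), with H2-Q4 at 0.58 and Tap2 at 0.47. MHC class II genes had a median of -0.15, which turned to 0.07 under the other scaling. H2-Ab1, a class II chain gene, was within 0.13 of control in each treated library. Inflammatory macrophage genes were higher in 13 of 17 (median 0.98, percentile 100), with Il1a at 3.59, Slc7a2 at 2.68 and Tnf at 0.99 (0.65 to 1.33). For Tnf, 1 cell held 21.1% of the UMIs, and 118 of 1868 cells had one against 103 of 1521 in control. Without that cell the ratio was 0.64. Cd40 (0.22, -0.0062 to 0.44) did not differ detectably at this depth but was at 0.30 (0.073 to 0.52) without 1 control cell, and Il1b (0.20, 0.14 to 0.26) became -0.09 when cluster 0 joined the class. Resident and alternatively activated genes were lower in 12 of 20 (median -0.55, percentile 0), with C1qa at -1.10, while Apoe was at 0.83. The monocyte list was split 7 to 7 (median 0.05), with Ly6c2 at 1.75, Hp (a leading gene of cluster 4) at 2.57, the fibronectin gene Fn1 at 2.35, Ifitm6 at -1.54 and Ccr2 at -0.97.

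The lists of glycolysis and hypoxia genes and of lysosome and lipid handling genes were higher with the combination, while oxidative phosphorylation genes moved little. Glycolysis and hypoxia genes were above control in 24 of 24 members (median 0.92, percentile 100), led by Egln3 (2.50), Hilpda (2.49) and Bnip3 (1.70). Lysosome and lipid handling genes were higher in 18 of 20 (median 0.75, percentile 100), with Gpnmb at 2.60, the lipid droplet gene Plin2 at 1.93, the fatty acid transporter gene Cd36 at 1.67 and Ctsd at 1.34. The chemokine list was higher in 14 of 20 (median 0.62, percentile 100), with Ccl17 at 5.14 and Cxcl3 at 2.70. Proliferation genes were lower in 20 of 20 (median -2.38, percentile 0; -1.72 without cluster 15), ribosomal protein genes in 22 of 22 (median -0.30, percentile 0.72) and mitochondrially encoded genes in 10 of 10 (median -0.52, percentile 0.16). Dissociation stress genes, which tissue digestion can induce, were higher in 16 of 18 (median 0.41, percentile 100), with Egr1 at 1.43 and Atf3 at 1.34. Among genes that reached 50 CPM, which Ccl17 and Il1a did not, the highest ratios were those of Chil3 (6.88, 6.55 to 7.23), Retnla (6.21, from 55 cells), Ccl24 (4.74), the activin subunit gene Inhba (3.71) and AA467197 (3.49). Cxcl13 was the lowest at -10.96 (-16.27 to -8.48), with 1 UMI in the combination library, followed by Ccnd1 (-4.69), the tetraspanin gene Cd81 (-3.79), Slamf9 (-3.56) and Cd72 (-3.35). Chil3, Inhba, Cd81 and Cd72 lead clusters of the class.

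**Figure D2:**
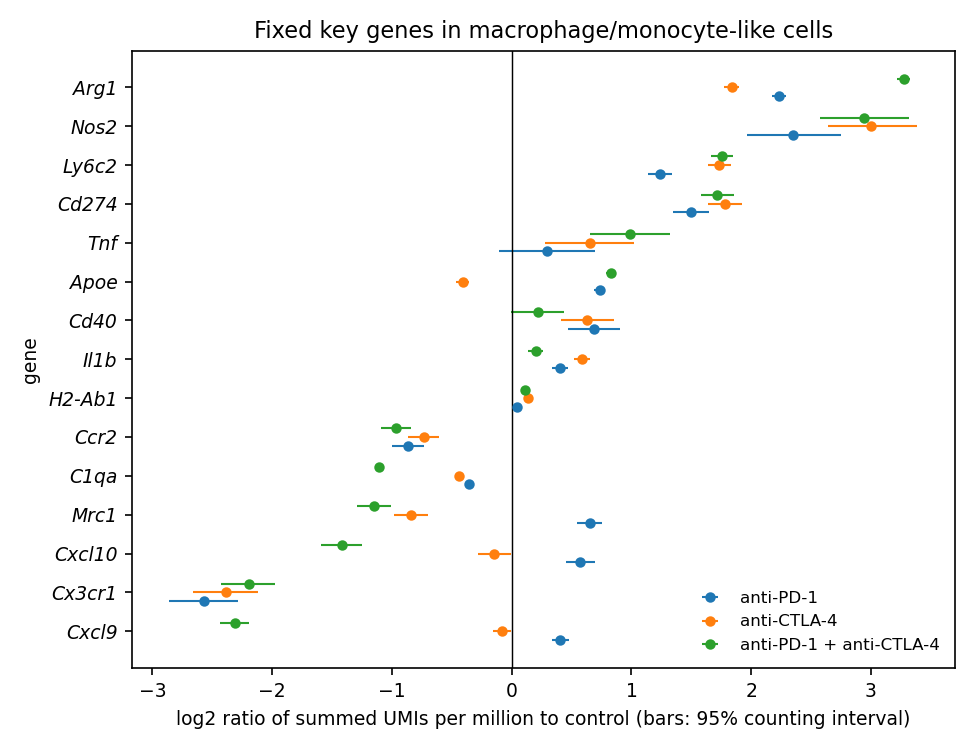
Log2 ratio to control of summed UMI counts (CPM) in macrophage/monocyte-like cells for the fixed key genes reported here, 1 point per treated library, with 95% exact intervals of counting error. Nos2 was at 2.35, 3.00 and 2.94 and Cx3cr1 at -2.57, -2.39 and -2.20 with anti-PD-1, anti-CTLA-4 and the combination.

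Compared directly, macrophage/monocyte-like cells of the combination library had more Arg1 than those of either single-antibody library, by 1.04 (1.01 to 1.07) against anti-PD-1 and 1.44 (1.40 to 1.47) against anti-CTLA-4. They had less Cxcl9, with log2 ratios of -2.72 (-2.84 to -2.60) and -2.24 (-2.36 to -2.11), and less C1qa (-0.75 and -0.66). Nos2 was 0.59 higher than with anti-PD-1 (0.37 to 0.81) and not detectably different from anti-CTLA-4 (-0.07, -0.26 to 0.12). Interferon-induced genes were lower in 29 of 32 members against anti-PD-1 (median -0.65, percentile 0) and in 31 of 32 against anti-CTLA-4 (median -0.60, percentile 0). Glycolysis and hypoxia genes were higher against both (medians 0.29 and 0.26, percentile 100). Mrc1 was at -1.80 against anti-PD-1 and -0.31 against anti-CTLA-4, and Apoe at 0.10 and 1.24. Besides Chil3 (2.78 and 3.32), Ltc4s, which encodes leukotriene C4 synthase, had the highest ratio among genes that reached 50 CPM in both comparisons (4.10, 3.41 to 4.90, and 3.36, 2.82 to 3.96). Against anti-PD-1, Gm26532 (1.82), Sgk1 (1.63) and Rgcc (1.52) were next highest and Cd163 (-3.50), Ccl24 (-3.09), Nov (-2.92) and Ch25h (-2.88) were lowest. Against anti-CTLA-4, Fn1 (1.95), Cav2 (1.61) and Cxcl3 (1.53) were next highest. Cxcl13 (-8.66, -13.97 to -6.17), Dnase1l3 (-2.69), H2-M2 (-2.62) and Nov (-2.11) were lowest there, but 1 cell held 74.7% of the 316 Cxcl13 UMIs of the anti-CTLA-4 library.

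The share of macrophage/monocyte-like cells with a Nos2 UMI, at 1000 UMIs per cell, was 1.65% in control (1.07 to 2.42), 4.42% with anti-PD-1 (3.33 to 5.72), 8% with anti-CTLA-4 (6.62 to 9.56) and 7.37% with the combination (6.20 to 8.68). Without thinning the shares were 3.35%, 12.5%, 17.2% and 17.02%. In T cell-like cells, taken as background, it was at most 0.452%. Cx3cr1 was seen in 8.11% of control cells (6.78 to 9.60), against 1.47%, 1.60% and 2.19% (1.56 to 2.99) in the treated libraries. The background was 1.36%, 1.12%, 1.23% and 0.723%, so the shares with anti-PD-1 and anti-CTLA-4 lay near those of T cell-like cells. That T cell-like cells make no Cx3cr1 or Cd274 of their own was assumed and not tested. Unthinned Cx3cr1 shares were 24.7%, 3.18%, 3.97% and 3.53%. Arg1 was seen in 16.9%, 53.9%, 44.3% and 69.5% of thinned cells (unthinned 31.3%, 69.5%, 60.0% and 80.8%), with backgrounds of 0.543%, 4.31%, 2.46% and 7.05%. Mrc1 was seen in 16.6%, 23.6%, 9.38% and 6.92% (unthinned 46.0%, 47.3%, 25.8% and 19.004%; background at most 1.12%). Cd274 was seen in 7.12%, 18.2%, 22.1% and 20.5% (unthinned 21.8%, 45.4%, 49.5% and 43.7%; background 2.81% to 4.07%). Median depths of these cells before thinning were 4306, 3750, 3441 and 3381.5 UMIs, against 1924, 2126, 2443 and 1868.5 in T cell-like cells. Shallower cells left out numbered 4, 33, 36 and 90 of the macrophage/monocyte-like and 2, 69, 39 and 150 of the T cell-like cells.

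In the GENCODE M21 annotation of GRCm38, the build also called mm10, Nos2 (ENSMUSG00000020826) lies on the plus strand of chromosome 11 from 78920787 to 78960254. Cx3cr1 (ENSMUSG00000052336) lies on the minus strand of chromosome 9 from 119901616 to 120069879. Arg1 lies on chromosome 10 from 24915221 to 24927484, Mrc1 on chromosome 2 from 14229392 to 14332057 and Cd274 on chromosome 19 from 29367455 to 29388095. Cxcl9, on chromosome 5 from 92321347 to 92328079, neighbours Cxcl10 at 92346638 to 92348889. Foxp3 (ENSMUSG00000039521) lies on chromosome X from 7573644 to 7595245 and Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892. Pdcd1 and Ctla4 are both on chromosome 1, from 94038305 to 94052553 and from 60887000 to 60915832. All 11 are protein-coding genes, and the UMIs come from the 3′ ends of their transcripts.

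T cell-like cells of the anti-PD-1 library had more Ifng transcripts, which encode interferon gamma, and fewer transcripts of Foxp3, the transcription factor gene of regulatory T cells, than control cells. Ifng was at 267 CPM (476 UMIs) against 108 CPM (296 UMIs), a log2 ratio of 1.31 (1.09 to 1.52), and 1 cell held 19.3% of its UMIs. Foxp3 was at 17.4 CPM (31 UMIs) against 47.4 CPM (130 UMIs), a log2 ratio of -1.45 (-2.06 to -0.87). The receptor genes Pdcd1 (-0.55, -0.72 to -0.38) and Ctla4 (-0.83, -1.04 to -0.62) were lower, and Lag3 (0.30) was higher. Havcr2 was at 0.48 (0.20 to 0.75), but 1 cell held 17.2% of its UMIs and without that cell it did not differ detectably (0.21, -0.086 to 0.50). The pore-forming gene Prf1 was 1.26 higher (0.70 to 1.83), with 18.6% of its 70 UMIs in 1 cell, and the granzyme gene Gzmb was at -0.30. The Cd4-led cluster 3 was the largest in each library (331, 221, 243 and 420 cells in control, anti-PD-1, anti-CTLA-4 and combination). The makeup of the rest of the class differed between libraries. Il7r-led cluster 6 held 18.4%, 27.6%, 24.3% and 32.6% of T cell-like cells in the same order, Cd8-led cluster 8 held 22.9%, 13.2%, 11.8% and 15.3%, and cycling cluster 9 held 12.4%, 15.5%, 26.2% and 11.5%. Regulatory T cell-like cluster 10, with Foxp3 seen in 28.0% and Cd4 in 23.8% of its cells over all libraries, held 16.4%, 11.8%, 6.23% and 7.25%. In clusters made here with the leading genes kept, its ratios to control stayed within counting error of these. In clusters made without leading genes, its log2 ratios were 0.95 with anti-PD-1 and 0.27 with anti-CTLA-4. In that run a cluster of 92 cells took its number, 65.2% of them from cluster 10, which had 403 cells. Those 2 values therefore cannot show how the whole cluster's share moved. The values given are differences of the whole class.

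Regulatory T cell genes were lower in 13 of 14 members with anti-PD-1 (median -0.74, percentile 0), with the integrin gene Itgae at -2.01, Ikzf2 at -0.65 and Klrg1 at -1.21. Klrg1 was at -2.20 and Il2ra, the exception at 0.18 (-0.14 to 0.50), was at -0.45 without the cycling cluster 9. Cytotoxic effector genes were higher in 14 of 20 (median 0.22, percentile 99.9), with Gzmc at 2.24. NK cell markers, of which Gzma and Prf1 are also on that list, were higher in 10 of 10 within this class (median 0.59). Interferon-induced genes were higher in 25 of 31 (median 0.18, percentile 98.9) and glycolysis and hypoxia genes in 16 of 23 (median 0.15, percentile 98.6). Inhibitory receptor and exhaustion genes had a median of -0.10 (6 of 14 higher), naive and memory T cell genes -0.12 (7 of 14), Th1 genes 0.12 (8 of 14) and interleukin-2 and costimulation genes 0.06 (8 of 14), all between percentiles 13.1 and 89.9. Tcf7, a gene of naive and memory cells, was 0.60 higher (0.15 to 1.06), Icos was at -0.45 and Cxcr6 at 0.19. The intervals of Tigit (-0.34), Tnfrsf9 (-0.12) and Mki67 (0.08) included 0. Proliferation genes were higher in 17 of 20 (median 0.13), but their median was -0.25 without cluster 9. Among the highest ratios of genes that reached 50 CPM were the T cell cytokine genes Ccl1 (3.46) and Csf2 (2.61) and the granzyme gene Gzmd (2.65, 2.17 to 3.17). In the anti-PD-1 library, 10 cells held 94.2% of the UMIs of Ccl1, 77.5% of those of Csf2 and 84.1% of those of Gzmd. Ccl24 (7.29, 4.78 to 12.61, with 1 UMI in control) and Arg1 (2.91) are macrophage genes. Arg1 in T cell-like cells stood at 3.62% of its macrophage/monocyte-like level, below the 7.43% of the macrophage gene Lyz2. The lowest ratios among genes that reached 50 CPM, which Itgae and Foxp3 did not, were those of Dapl1 (-2.25), Sh2b1 (-1.37), Sit1 (-1.34), Klrg1 and Rgs2 (-1.17). In control, 1 cell held 32.2% of the Sh2b1 UMIs.

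T cell-like cells of the anti-CTLA-4 library had little Foxp3, at 8.01 CPM (20 UMIs) and a log2 ratio of -2.57 to control (-3.32 to -1.88). Pdcd1 (-0.83, -0.99 to -0.67), Ctla4 (-0.47, -0.64 to -0.30), Icos (-0.68), Tnfrsf9 (-0.59) and Lag3 (-0.35) were lower, and Havcr2 was 0.41 higher. Prf1 was 1.23 higher (0.70 to 1.77). Ifng (0.20, -0.04 to 0.43) did not differ detectably from control. Its ratio was 0.33 (0.092 to 0.57) without the control cell with the most Ifng UMIs, -0.039 without the anti-CTLA-4 cell with the most, and 0.84 without the cycling cluster 9. Gzmb (0.09) was at -0.35 in thinned cells and -0.46 without cluster 9, and Mki67 (0.59, 0.31 to 0.88) was at -0.42 without it.

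Regulatory T cell genes were lower in all 14 members with anti-CTLA-4 (median -0.84, percentile 0), with Itgae at -3.23, Ikzf2 at -1.13 and Il2ra at -0.54. The ratio of Foxp3 was -1.97 when each cell had equal weight. Inhibitory receptor and exhaustion genes were lower in 10 of 14 (median -0.39, percentile 0.14), with Tox at -0.98. Interferon-induced genes were lower in 22 of 31 (median -0.24, percentile 0.445), with the GTPase gene Iigp1 at -1.25. Glycolysis and hypoxia genes were higher in 19 of 23 (median 0.34, percentile 99.99), with Hilpda at 1.88 and Pgk1 at 0.97. Proliferation genes were higher in 20 of 20 (median 0.57, percentile 100), with Mcm3 at 1.16, and had a median of -0.04 without cluster 9. Ribosomal protein genes were higher in 19 of 22 (median 0.15, percentile 97.4) and naive and memory genes had a median of -0.27 (percentile 2.19). Cytotoxic effector genes (median 0.08) and Th1 genes (0.07) lay within the range of random lists, at percentiles 77.5 and 73.2, with Gzmc at 2.21 and Bhlhe40 at 1.31. MHC class II genes were lower in 9 of 10 (median -0.94, percentile 0) together with the macrophage or monocyte markers (16 of 16 lower, median -1.20). Macrophage genes were also among the lowest ratios of genes that reached 50 CPM, with Ms4a7 at -3.08, C1qa at -1.68, Tgfbi at -1.68 and Cd14 at -1.64, beside the regulatory T cell gene Izumo1r (-1.94). The level of the macrophage gene Lyz2 in T cell-like cells was 6.19%, 7.43%, 3.02% and 5.47% of that in macrophage/monocyte-like cells in control, anti-PD-1, anti-CTLA-4 and combination. The highest ratios of such genes included Gzmd (3.27), Csf2 (2.68) and Gzme (2.57), whose 29 control UMIs came from 10 cells. In the anti-CTLA-4 library, 10 cells held 78.6% of the Gzmd, 63.1% of the Csf2 and 80.3% of the Gzme UMIs. The mast cell protease genes Cpa3 (153 UMIs against 0 in control) and Cma1 (225 against 7, 5.14) came from 3 and 6 cells of the class.

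In the combination library, T cell-like cells had more Ifng than control cells (238 CPM, 713 UMIs, log2 ratio 1.14, 0.94 to 1.34) and less Foxp3 (10.3 CPM, 31 UMIs, -2.20, -2.81 to -1.62) and Pdcd1 (-1.19, -1.36 to -1.03). For Ifng, 1 cell held 21.6% of the UMIs. Ctla4 (0.07, -0.08 to 0.22) did not differ detectably. Gzmb was at -0.65 (-0.71 to -0.59), Il2ra at -0.75, Tnfrsf9 at -0.79 and Lag3 at -0.50. Tcf7 (0.66, 0.26 to 1.06), Havcr2 (0.54) and Cxcr6 (0.43) were higher. Prf1 was at 21.7 CPM (65 UMIs) against 16.4 CPM (45 UMIs) in control, and the intervals of these 2 levels overlapped.

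Regulatory T cell genes were lower in 13 of 14 members with the combination (median -0.89, percentile 0), with Itgae at -2.18, Ikzf2 at -1.66 and Capg at -1.41. Th1 genes were higher in 10 of 14 (median 0.36, percentile 100), with Bhlhe40 at 1.32 and the cytokine gene Il2 at 0.64. Cytotoxic effector genes went both ways, 11 of 20 higher with a median of 0.44, including Gzmc (1.45), Klrd1 (-1.57) and Klrk1 (-1.19). The NK cell markers were lower in 8 of 10 in this class (median -1.11). Glycolysis and hypoxia genes were higher in 22 of 24 (median 0.39, percentile 100), with Hilpda at 1.89. Interferon-induced genes were lower in 22 of 31 (median -0.19, percentile 1.47), with Cxcl9 at -1.83 and Iigp1 at -1.50. Cxcl9 in T cell-like cells stood at 6.39% of its macrophage/monocyte-like level in control and 8.92% in the combination, beside 6.19% and 5.47% for Lyz2. Naive and memory genes had a median of -0.01, with Klf2 at 1.95 and S1pr1 at 1.12. The inhibitory receptor list (median -0.16, with Cd160 at -1.20), the interleukin-2 and costimulation list (0.14, with Cd40lg at 1.81) and the proliferation list (-0.10) lay at percentiles 8.04, 97.4 and 9.45. Dissociation stress genes were higher in 18 of 18 (median 0.53, percentile 100), with Nfkbiz at 1.39 and Junb at 1.18. Mitochondrially encoded genes were lower in 9 of 10 (median -0.43, percentile 0) and ribosomal protein genes higher in 22 of 22 (median 0.09, percentile 98.1). The highest ratios among genes that reached 50 CPM were those of the macrophage genes Chil3 (5.27), Arg1 (4.22) and Mmp12 (3.45), then of the protease gene Furin (2.45) and of Gzmd (2.02), for which 1 cell held 69.6% of the UMIs. Chil3 and Arg1 stood at 5.53% and 4.35% of their macrophage level, close to the 5.47% of Lyz2. The lowest of such genes were Klra5 (-2.22), Dapl1 (-2.16), Ms4a7 (-2.06), the chemokine gene Xcl1 (-1.90, with 28.2% of the control UMIs in 1 cell) and Wls (-1.82).

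**Figure D3:**
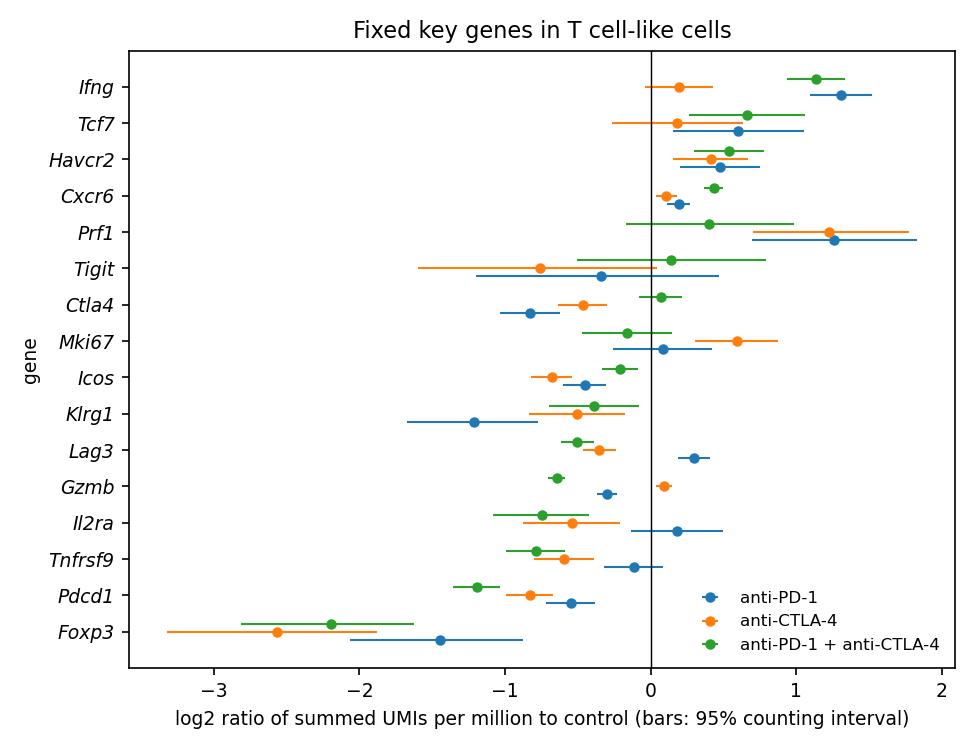
Log2 ratio to control of summed UMI counts (CPM) in T cell-like cells for the fixed key genes, 1 point per treated library, with 95% exact intervals of counting error. Foxp3 was at -1.45, -2.57 and -2.20 and Ifng at 1.31, 0.20 and 1.14 with anti-PD-1, anti-CTLA-4 and the combination.

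Against the single antibodies, T cell-like cells of the combination library had more Ctla4 (0.90, 0.70 to 1.10, against anti-PD-1 and 0.54, 0.37 to 0.70, against anti-CTLA-4) and less Pdcd1 (-0.64 and -0.36) and Gzmb (-0.35 and -0.74). Ifng was 0.94 higher than with anti-CTLA-4 (0.75 to 1.14). Foxp3 did not differ detectably from either (-0.75, -1.52 to 0.02, and 0.37, -0.49 to 1.26). The regulatory list had medians of -0.30 against anti-PD-1 (percentile 0.47) and 0.23 against anti-CTLA-4 (percentile 99.0). Dissociation stress genes were higher against both (medians 0.45 and 0.49, percentile 100). Proliferation genes were lower in 20 of 20 against anti-CTLA-4 (median -0.66, percentile 0). NK cell markers were lower in 10 of 10 against each (medians -1.68 and -1.50), and Ncr1 (-2.97), Xcl1 (-2.31) and Iigp1 (-1.92) were among the lowest ratios of genes that reached 50 CPM against anti-PD-1, with Spp1 (-2.62) and Ccl24 (-2.52). Mllt3 (1.50), Gm26532 (1.74) and Ier3 (1.45) were among the highest against anti-PD-1 and Ccl6 (1.73) and N4bp1 (1.67, with 28.8% of its UMIs in 1 cell) against anti-CTLA-4, beside Chil3 and Mmp12. Against anti-CTLA-4 the lowest were Cma1 (0 against 225 UMIs), Cpa3 (-7.52, -12.84 to -5.02, 1 against 153 UMIs), Spp1 (-2.25), Gzme (-1.95) and Xcl1 (-1.77).

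The share of T cell-like cells with a Foxp3 UMI at 1000 UMIs per cell was 5.07% in control (3.85 to 6.53), 1.60% with anti-PD-1 (0.769 to 2.92), 0.683% with anti-CTLA-4 (0.222 to 1.59) and 0.814% with the combination (0.373 to 1.54). It was at most 0.0659% in macrophage/monocyte-like cells, the background class. Unthinned shares were 8.58%, 3.31%, 1.69% and 1.59%. Pdcd1 was seen in 21.1%, 17.1%, 16.7% and 11.03% (unthinned 34.4%, 27.6%, 30.7% and 21.4%) and Ctla4 in 16.2%, 11.7%, 12.98% and 19.98% (unthinned 28.2%, 24.5%, 31.9% and 32.7%), with backgrounds of at most 0.844%. Ifng was seen in 5.97% (4.65 to 7.54), 9.11%, 8.33% and 11.8% (10.0 to 13.9; unthinned 12.3%, 14.7%, 17.3% and 17.99%; background at most 0.281%). No order is read between anti-PD-1 and the combination, whose CPM values ran the other way. The shares of Icos (27.1%, 22.4%, 23.4% and 27.8%; unthinned 43.7%, 39.4%, 42.7% and 43.9%; background at most 0.593%) and Gzmb (43.4%, 36.7%, 37.98% and 34.9%; unthinned 52.9%, 46.0%, 50.1% and 41.2%; background at most 2.62%) did not follow their CPM throughout and are given without an order. Mki67 was seen in 3.17%, 4.15%, 5.33% and 2.89% of cells (unthinned 8.85%, 10.5%, 17.8% and 7.72%), against 2.24%, 1.39%, 1.24% and 0.956% in macrophage/monocyte-like cells, part of which belong to the cycling cluster 15.

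**Figure D4:**
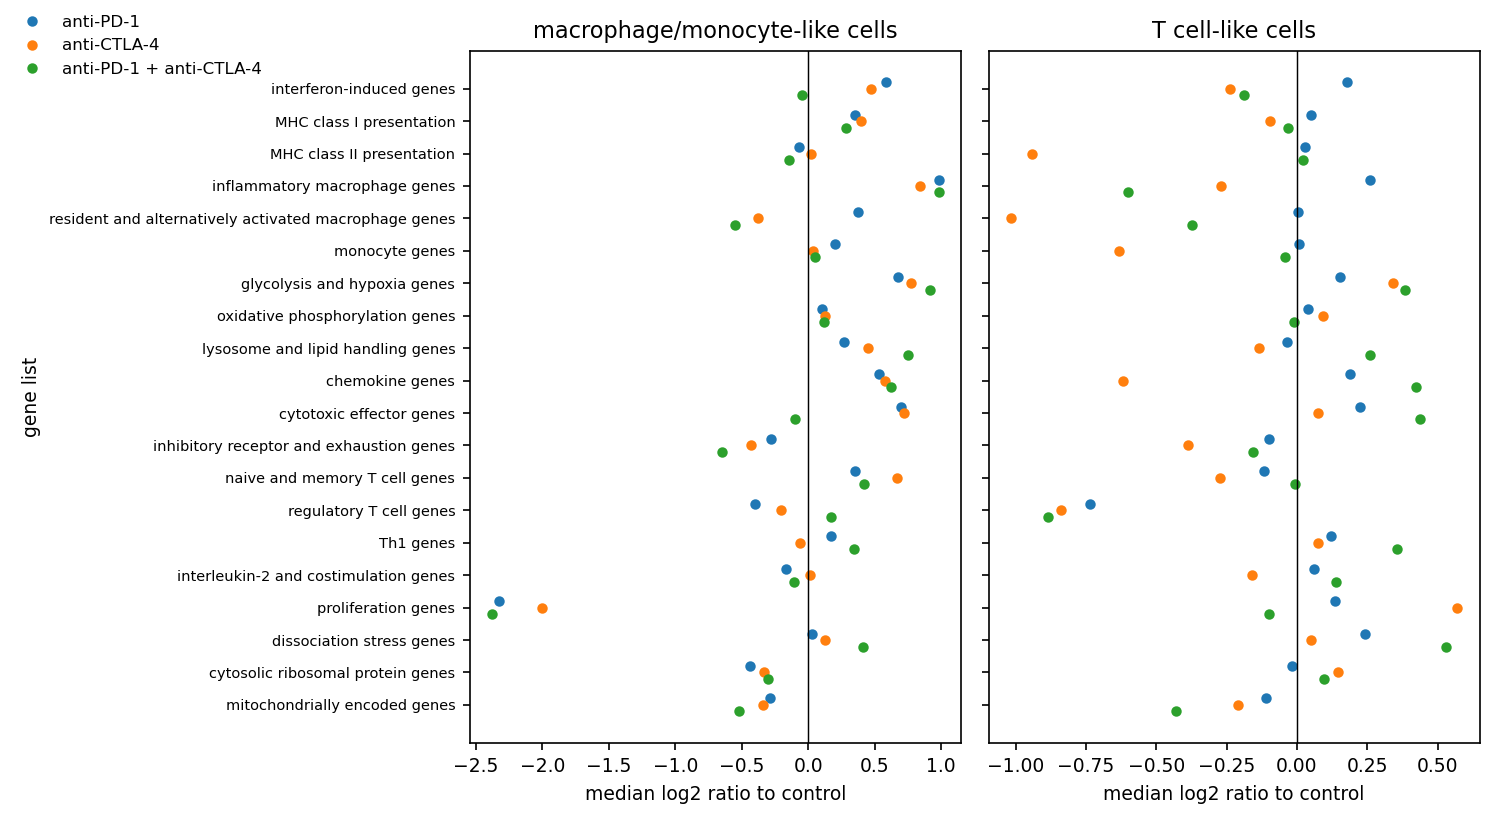
Median log2 ratio to control of each fixed gene list in macrophage/monocyte-like and T cell-like cells, 1 point per treated library, with a log2 axis of its own for each panel. In macrophage/monocyte-like cells the interferon-induced median was 0.59, 0.47 and -0.04 with anti-PD-1, anti-CTLA-4 and the combination, the last of these turning to 0.17 under median-of-ratios scaling, and in T cell-like cells the regulatory median was -0.74, -0.84 and -0.89.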

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

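The tests of the cluster mix, of cells with T or NK cell UMIs, of dilution among all listed cells and of handling, and the list medians without cycling clusters, were chosen only after the results were seen; the bounds of the tests of depth and of doublet scores were written after the ratios but before those tests were run. Leaving out the highest doublet scores was itself chosen after the data were seen. The difference between macrophage/monocyte-like and T cell-like cells was not tested for any list below.

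In 5 cases the interval of a list's median, taken from the spread of its members, lay wholly above control in one class and wholly below it in the other. Proliferation genes had a median log2 ratio of -2.33 in macrophage/monocyte-like and 0.13 in T cell-like cells with anti-PD-1, and of -2.01 and 0.57 with anti-CTLA-4. Interferon-induced genes were at 0.47 and -0.24 with anti-CTLA-4, where macrophage transcripts in T cell-like cells were also fewer (Lyz2 at 3.02% of its macrophage/monocyte-like level against 6.19% in control). Ribosomal protein genes were at -0.33 and 0.15 with anti-CTLA-4 and at -0.30 and 0.095 with the combination. Relative to median-of-ratios scaling, macrophage/monocyte-like ratios given here are shifted by -0.16 with anti-CTLA-4 and -0.21 with the combination. That is a large part of both ribosomal medians of that class, though less than the whole. Without the cycling clusters the proliferation medians of T cell-like cells were -0.25 with anti-PD-1 and -0.043 with anti-CTLA-4, while those of macrophage/monocyte-like cells were -1.10 and -1.26, so the opposite directions of that list rest on T cell-like cluster 9.

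The higher Nos2 and lower Cx3cr1 of macrophage/monocyte-like cells in all 3 treated libraries were weighed against technical causes. Thinning every cell to 1000 UMIs left the smallest of the 6 absolute log2 ratios at 1.51. These ratios are already divided by the UMI total of the class, so thinning mainly gives each cell equal weight. The thinned ratio therefore could not decide whether depth plays a part. Leaving out the cells with a UMI of a T or NK cell marker, between 18.3% and 23.2% of the class, left the smallest ratio at 2.26. The removal moved Cx3cr1 from -2.57 to -2.92 with anti-PD-1 and from -2.20 to -2.64 with the combination, and the other 4 ratios stayed within counting error. T cell-like cells held few Nos2 UMIs, so doublets with them would mainly dilute that gene. With each single antibody their Cx3cr1 share lay near that of the class, so doublets would change Cx3cr1 little there. The removal therefore could not decide about such doublets. The levels of both genes in NK cell-like cells are not given here, and no conclusion is drawn for doublets with them. Doublets with other cells cannot be told apart from the pattern. Leaving out the highest doublet scores left the ratio at 2.22 but moved no result outside its interval, and Scrublet's own threshold marked 1 cell. A change in the mix of the authors' clusters alone, with each cluster at its control level, gave 69.0%, 59.05% and 74.0% of the Nos2 ratios of anti-PD-1, anti-CTLA-4 and the combination and 34.6%, 32.2% and 64.0% of the Cx3cr1 ratios. For Cx3cr1 with a single antibody the upper bound, for counting error only, was 41.3%, which argues against that mix as the whole cause there. For Nos2 (upper bound 88.4%) and for Cx3cr1 with the combination (74.6%), a changed mix and a change within clusters cannot be told apart. These upper bounds leave out the spread between cells, and 1 cell held 16.2% of the Nos2 UMIs of the anti-PD-1 library. The bounds of this test were set 4 times. The lowest of all 6 percentages against 50%, set before the percentages were computed, counted against the mix for the pattern as a whole. After they were seen, the same bound for each gene left Nos2 open, the upper bound against 100% counted against the mix for both genes, and the upper bound against 50% gave the reading above. The treatment stays open as an untested explanation, as do library and batch, since each group is 1 library.

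The lower share of T cell-like cells with a Foxp3 UMI in each treated library was weighed against depth and dilution. At 1000 UMIs per cell the highest upper bound of the 3 share ratios to control was 0.624, which argues against depth. Among all listed cells at that depth, T cell-like cells with a Foxp3 UMI were 1.48% of the control library and 0.310%, 0.156% and 0.248% of the anti-PD-1, anti-CTLA-4 and combination libraries, with a highest upper bound of 0.415 for the ratios. Dilution by other T cells, with as many Foxp3 cells left, would have reached 1. The ratios of the whole T cell-like share to control were 0.697, 0.792 and 1.09. The result among all listed cells therefore largely follows from shares already given and adds no separate support. Fewer regulatory T cells, less Foxp3 per cell and a difference between libraries of another origin remain open.

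Dissociation stress genes were higher in the combination library than in control in both main classes. A difference in handling of the whole library would raise them in every class, and the median was above 0 in 8 of 10 classes with enough UMIs. The exceptions were cluster 14 (-0.19) and plasmacytoid dendritic cell-like cells (-0.41), while the other classes ranged from 0.05 in cluster 13 to 0.95 in migratory dendritic cell-like cells. Handling and treatment cannot be told apart here, since each group is 1 library.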

How the results depend on the processing

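The doublet score, T or NK cell UMI, leading-gene, joined-cluster, list cycling and left-out-cell alternatives were chosen only after the data were seen; the others were planned. Of 207 recomputed values of the 27 main results, 171 stayed within the interval of the value given, 31 moved and 5 reversed. Of 1786 values of 240 other results, 1535 stayed, 242 moved and 9 reversed. That interval covers counting error, except for list medians, where it comes from the spread of the list's members. The planned doublet alternative with Scrublet's own threshold gave no value. No paired analysis was possible because each group has 1 library and the results come from no test. Unless said otherwise, the cause was not tested. Depth limits genes such as Foxp3 and Tigit, with 47 or fewer UMIs in each treated library.

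Log2 ratios of macrophage/monocyte-like shares depended on how cells were classed. The gene gates count a wider class, as they also take in most of cluster 0 and other cells with Lyz2. For anti-PD-1 (-0.13) gene gates gave 0.24, clusters without leading genes 0.028 and all barcodes -0.0070. For anti-CTLA-4 (0.08) all barcodes gave -0.091, clusters made here -0.16 and gates 0.19. For the combination (0.24) gates gave -0.058, all barcodes 0.018, clusters made here 0.012 and clusters without leading genes 0.11. In clusters without leading genes, the share of regulatory T cell-like cluster 10 within T cell-like cells turned from -0.48 to 0.95 for anti-PD-1. It turned from -1.40 to 0.27 for anti-CTLA-4 and moved from -1.18 to -0.40 for the combination. That construction removes the genes defining the cluster, and 92 cells took its number, 65.2% of them from the 403 of cluster 10. These values cannot show the direction for the whole cluster. In clusters made here with the leading genes kept, its ratios stayed within counting error.

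The Nos2 ratio of anti-PD-1 was 1.51 in thinned cells, 1.92 in clusters without leading genes and 1.69 with cluster 0 added. For anti-CTLA-4 the same settings gave 2.33, 2.58 and 2.38, and clusters made here 3.52. For the combination, thinning gave 2.07, clusters made here 3.48 and cluster 0 added 2.52. Without cells that held T or NK cell UMIs, Cx3cr1 was at -2.92 for anti-PD-1 and -2.64 for the combination. It was at -2.04 with cluster 0 added for anti-PD-1, at -1.92 with equal weight per cell and -2.02 in thinned cells for anti-CTLA-4, and at -1.66 in thinned cells for the combination. Ifng without cycling cluster 9 was at 1.80, 0.84 and 1.52 in the 3 comparisons, and at 0.50 in thinned cells for anti-CTLA-4. Without the treated cell with the most Ifng UMIs it was at 1.00, -0.039 and 0.79.

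Among single genes and lists, median-of-ratios scaling turned Cxcl9 and Cxcl10 with anti-CTLA-4 in macrophage/monocyte-like cells to 0.079 and 0.010, by its shift of the whole class. Cluster 0 added turned Il1b with the combination to -0.087. In T cell-like cells with anti-CTLA-4, Gzmb turned to -0.35 with equal weight per cell, to -0.35 in thinned cells and to -0.46 without cluster 9, and Mki67 to -0.42 without it. Leaving out cluster 9, which removes most cycling cells, turned the proliferation list of T cell-like cells to -0.25 for anti-PD-1 and -0.043 for anti-CTLA-4.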

Other observations

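Departures from additivity were planned, and the profiles of cluster 0 and NK cell-like cells and the search for barcodes with markers of both lineages were chosen after the data were seen. Cells of cluster 0, which carried macrophage markers such as Lyz2, Csf1r and Ly6c2, had more Arg1 than control in each treated library (2.71 with anti-PD-1, 1.68 with anti-CTLA-4, 3.27 with the combination) and more Cd274 (1.09, 0.89 and 0.92). Ly6c2 was higher as well (0.59, 1.19 and 0.50). Cxcl9 was lower, with log2 ratios of -0.32, -0.92 and -2.20. Nos2 was not detectably different in anti-PD-1 (-0.19, -0.83 to 0.45), anti-CTLA-4 (-0.019, -0.69 to 0.66) or the combination (-0.68, -1.85 to 0.36), unlike in macrophage/monocyte-like cells, although that contrast was not tested. Interferon-induced genes had medians of 0.37 (percentile 100), 0.12 (percentile 91.3) and 0.06 (percentile 78.1).

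NK cell-like cells had more Gzmb with anti-PD-1 (1.61, 1.50 to 1.72) and anti-CTLA-4 (0.96, 0.83 to 1.08) and less with the combination (-0.50, -0.69 to -0.31). Prf1, the perforin gene, followed with 1.33, 0.93 and -0.22. Klrg1, a receptor of mature NK cells, was higher in all 3 (1.35, 1.40 and 1.78), and the chemokine receptor gene Cxcr6 was at -0.22, 1.19 and 1.66. Cytotoxic effector genes had medians of 0.32 (percentile 99.97), 0.39 (percentile 99.99) and -0.04 (percentile 43.4), and glycolysis and hypoxia genes of 0.27, 0.48 and 0.51.

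Some genes were far from the sum of the single-antibody log2 ratios in the combination library. In macrophage/monocyte-like cells the largest departures were those of Ccl24 (-9.22), Nov (-7.12), Ltc4s (5.31), Apol7c (-4.64) and Retnla (-4.39). Ltc4s had 95, 17, 29 and 382 UMIs in control, anti-PD-1, anti-CTLA-4 and combination, but 1 control cell held 49.5% of the control UMIs. Without that cell its log2 ratios to control were -0.99, -0.27 and 3.07 and its departure 4.33. Ccl24, Nov, Apol7c and Retnla were above control in all 3 treated libraries, by less in the combination than the single-antibody ratios add up to. The 20 control UMIs of Retnla came from 4 cells. In T cell-like cells Cpa3, Cma1, Ccl24 (-6.93), Spp1 (-4.28) and Gzme (-4.12) departed most. Cpa3 and Cma1 came from few cells and depend on the 0.5 added to counts of 0. Ccl24 had 1 control UMI and came from 9 cells of the combination, Gzme came from 10 control cells, and 1 cell held 57.2% of the Spp1 UMIs of the combination. Ccl24 and Spp1 are made by macrophages.

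Other cell type markers gave further values. In macrophage/monocyte-like cells the 4 measured mast cell or basophil markers were at -4.30, -2.14 and -5.48 with anti-PD-1, anti-CTLA-4 and the combination. Few cells carry markers of that list. Over all libraries, Cpa3 was seen in 3 cells of cluster 1 and 1 cell of cluster 4, and Mcpt8 in at most 3 cells of any cluster of the class. In T cell-like cells the mast cell or basophil markers were at 6.24 with anti-CTLA-4 (3 of 3 higher). Of these markers, Cpa3 had 153 UMIs from 3 cells, with 52.9% in 1 cell, so the value does not describe the class. Innate lymphoid cell type 2 markers in T cell-like cells were at 1.24, 0.18 and 0.95. Cd3d in macrophage/monocyte-like cells stood at 0.699%, 0.736%, 0.594% and 1.09% of its T cell-like level in control, anti-PD-1, anti-CTLA-4 and combination.

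Barcodes with UMIs of both Cd3 and C1q genes above a fixed minimum were 49.2%, 51.2%, 47.6% and 55.7% of cluster 13 in the 4 libraries, against 2.11%, 1.49%, 0.749% and 1.75% of all listed cells. Of the barcodes that the authors did not list, 10 of 47, 3 of 23, 1 of 36 and 3 of 21 had both. Cluster 13 also held 64.4% of its cells among the 3% highest doublet scores.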
